A study of Homo sapiens with 40 samples.

How the data were processed

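The data were deposited tables of estimated counts per transcript isoform from nanopore sequencing of 3 human cell lines. SH-SY5Y is a neuroblastoma line, and BT549 and T47D are breast cancer lines. Per the file headers, the authors made the values with ESPRESSO 1.4.0, which assigns reads to annotated and newly assembled isoforms and gives each isoform an estimated count, so a read that fits several isoforms is divided among them. Per the submitters' processing notes, the reads had been aligned to GRCh38 with minimap2 2.25. Isoform discovery was joint across the libraries of a table, so an isoform found in 1 library could collect counts in all. Per the labels' protocols, total RNA was extracted with TRIzol, cDNA was made by template switching and amplified by PCR, direct RNA libraries were made with the SQK-RNA004 kit, and the SIRV-Set 4 spike-in mix was added to the SH-SY5Y RNA. The strand used in counting was not given in the sources used here.

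The contents of a pair of the SH-SY5Y tables were the reverse of what their names say. The table named for downsampled on-target counts held counts of spike-in transcripts for the 26 single libraries, and the table named for spike-ins held human counts in 291 genes for 6 pooled columns. Both were used by content. The 291 genes of the pooled table served as the listed target genes, since they are the genes the authors kept as on-target. The labels name no fraction of a flow cell for the main cDNA libraries, and these are called the main cDNA set here.

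The SH-SY5Y table held 366428 transcripts of 27389 genes in 26 libraries of 12 groups, and 272721 transcripts were not annotated. Total counts ran from 0.351 M to 11.6 M per library. Entries with no gene held 0.402% to 1.10% of the counts and entries naming several genes 0.443% to 1.90%; both stayed out of library sizes and tests. No column was without a sample. The 14 pooled columns, 1 per method and cell line, have no replicates and were compared without a test.

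Counts were summed per gene, rounded to whole numbers and tested with edgeR 4.0.16 (quasi-likelihood F test, two-sided) in a single fit with a mean for each of the 12 groups. Genes had to pass filterByExpr, which left 275 listed and 13921 unlisted genes. TMM scaling was used, and expression is given as CPM on the TMM-scaled library sizes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast. Standard errors (SE) of log2 folds were the fold divided by the square root of F. Shares and yields were compared by exact two-sided permutation of the group labels. The p-values measure only the spread between these samples, since the labels do not say whether replicates were separate cultures. Intervals and floors cover counting error only, since the reads carry no molecular identifiers. Shares of single columns have exact Clopper-Pearson 95% intervals, and a count of 0 allows up to 3 counts.

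On simulated data with the fitted dispersions, 200 of 13838 genes were changed by a log2 fold of 0.5, 1 or 2. For the gene-based design against control, 29 of 67, 58 of 67 and 65 of 66 were recovered, with 8 of 13638 unchanged genes called. At 40 fmol the recovered genes were 17 of 67, 50 of 67 and 63 of 66, with 13 unchanged genes called, and in direct RNA 6 of 67, 33 of 67 and 64 of 66, with 3. Changed genes were drawn above a minimum of control counts, and each gene had the same dispersion in all groups. The real 40 fmol gene-based libraries differed more, with a chi-square per degree of freedom of 21.2 against 1.16 in the main gene-based pair. The simulated counts may therefore not hold for the 40 fmol libraries.

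Isoform usage was tested in listed genes with edgeR's diffSpliceDGE gene-level F test, on 2109 transcripts of 211 genes. Simulated usage changes, 30 genes in each of 5 draws, gave 149 of 150 recovered and 12 of 161 calls unchanged for the gene-based design. At 40 fmol 127 were recovered and 23 of 150 calls were unchanged, and in direct RNA 136 were recovered and 45 of 181 calls were unchanged. These are 7.45%, 15.3% and 24.9% of the calls, all above the nominal 5%. The Simes test on the same draws gave 17 of 153 (11.1%), 32 of 159 (20.1%) and 2 of 137 (1.46%) unchanged. Both tests thus call too many genes except Simes in direct RNA, but the gene-level 12 of 161 lies too near 5% to show an excess. Isoform distances were the mean over genes of the total variation distance between isoform shares after thinning each gene to 50 counts. Isoforms were called detected at 3 or more counts, in libraries thinned to a common depth of listed counts.

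The lists of genes were fixed before the data were examined. The 8 splicing lists were SR proteins, hnRNPs, tissue-regulated splicing factors, U1 and U2 snRNP and 3′ splice site factors, tri-snRNP and PRP19 complex proteins, Sm and LSm proteins, exon junction complex and mRNA export genes, and other splicing RNA-binding proteins, helicases and kinases. The last list has 42 symbols, and MATR3 has 2 gene identifiers in the table, so 43 genes were tested. The 6 lists of genes expected off target were cytosolic ribosomal proteins, mitochondrial mRNAs, noradrenergic, mesenchymal, breast epithelial and synaptic markers. Fewer than 5 mitochondrial mRNAs passed the filter, so that list was not tested. The 8 lists for the breast cancer panel were luminal and hormone receptor genes, receptor tyrosine kinases with mesenchymal-associated genes, PI3K-AKT-mTOR, RAS-MAPK, cell cycle, homologous recombination and checkpoint, mismatch repair, and chromatin regulators. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, over 195 pairs of list and contrast. In the pooled tables a list's median was placed among 10000 random lists of equal size drawn from genes with at least 100 counts. Because the study chose its targets, the splicing lists are not independent evidence for enrichment.

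Named genes were picked by rule. In each contrast with a control they were the 8 highest and 6 lowest log2 folds of listed genes, and the 6 highest and 4 lowest of unlisted genes, among genes called with groups that did not overlap. Between designs and for differences of effects the rule took the 5 highest and 5 lowest. For isoform usage it took the 6 genes with the lowest adjusted p and 2 transcripts each. For pooled tables it took the 6 highest and 6 lowest share ratios with at least 100 counts. The text gives a part of these.

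Alternatives tried were library-total and RLE scaling, DESeq2 1.42.0, no expression filter, a fit of only the groups compared, replicate number as a block, a crossed block, annotated transcripts only, a 5% share minimum, the Simes test, detection at 1 or 10 counts or at deposited depth, thinning to 100 counts, the fixed splicing lists in place of the listed genes, the most abundant transcript as length, at least 100 counts in the control column of pooled tables, and leaving out each library. Replicate numbers gave no clear sign of pairing, since residuals of libraries with the same number correlated between -0.332 and 0.295 over 12 pairs of groups. With 1 difference between replicates per group, pairing cannot be excluded. Other software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3 and limma 3.58.1.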

Results

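Adaptive sampling reads the start of each molecule in the pore and ejects molecules that match no target, and TEQUILA-seq captures targets with probes before sequencing. The SH-SY5Y libraries ask how far each raises the targeted genes, a set centred on splicing factors and other RNA-binding proteins. Of the 291 listed genes, 143 are on the fixed splicing lists, and among the other 148 are neighbours, pseudogenes and antisense transcripts of splicing genes. In the main cDNA set, unenriched control libraries held 3.25% ± 0.0433 (SD, n = 4) of their counts in listed genes, and TEQUILA libraries held 93.3% ± 1.70 (SD, n = 2). The gene-based design reached 5.23% ± 0.0131, the master-based 7.42% ± 0.140, the transcript-based 4.15% ± 0.147 and the exon-based 3.54% ± 0.0917, each with 2 libraries. All 8 adaptive sampling libraries together held 5.09% ± 1.58, and each lay above every control, at 3.48% to 7.52% against 3.21% to 3.31%. The exact two-sided permutation test gave p = 0.0384 over 495 splits. It also counts splits that place the highest libraries in the smaller group, so this p reflects the spread among the designs too. That p rose above 0.05 when any of 6 libraries was left out, namely each of the 4 controls and both gene-based libraries. The differences then were 1.82 to 1.86 percentage points against 1.84, still without overlap. Each design alone reached p = 0.0667 by the same exact permutation test, the smallest its 15 splits allow.

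Counts of listed genes, in place of their share, were higher by like amounts in all 4 designs. The labels give no flow-cell fraction for the main set, and half-flow-cell controls held 258.4 k and 313.9 k listed counts without enrichment, so run output and enrichment are not separated in these yields. The 8 adaptive sampling libraries held 279.8 k ± 38.1 counts in listed genes against 136.0 k ± 7.58 in the controls, a ratio of 2.06 (exact two-sided permutation test, p = 0.00202, the smallest of 495 splits). By design the mean yields were 290.3 k ± 85.8 for gene-based, 298.3 k ± 23.4 for master-based, 275.8 k ± 7.97 for transcript-based and 254.8 k ± 0.989 for exon-based libraries. The exon-based design thus yielded 1.87 times the control with a share only 1.09 times the control, since its libraries totalled 7.29 M ± 0.16 counts against 4.25 M ± 0.28. TEQUILA yielded 10480.1 k ± 1.43, or 77.1 times the control. In the half-flow-cell libraries the gene-based design raised the share from 3.24% ± 0.0319 to 4.63% ± 0.409 (exact two-sided permutation test, p = 0.0286, the smallest of 70 splits), while the yields over both loads were 265.0 k ± 12.4 and 286.1 k ± 33.4 (exact permutation test, p = 0.314). That test mixes the loads, and at 40 fmol alone the gene-based yields of 268.6 k and 271.6 k lay below the control yields of 313.0 k and 314.8 k. Leaving out control replicate 1 or 2 at 20 fmol, or control replicate 1 at 40 fmol, lifted that p above 0.05, with differences of 1.38, 1.39 and 1.39 percentage points against 1.39.

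**Figure D1:**
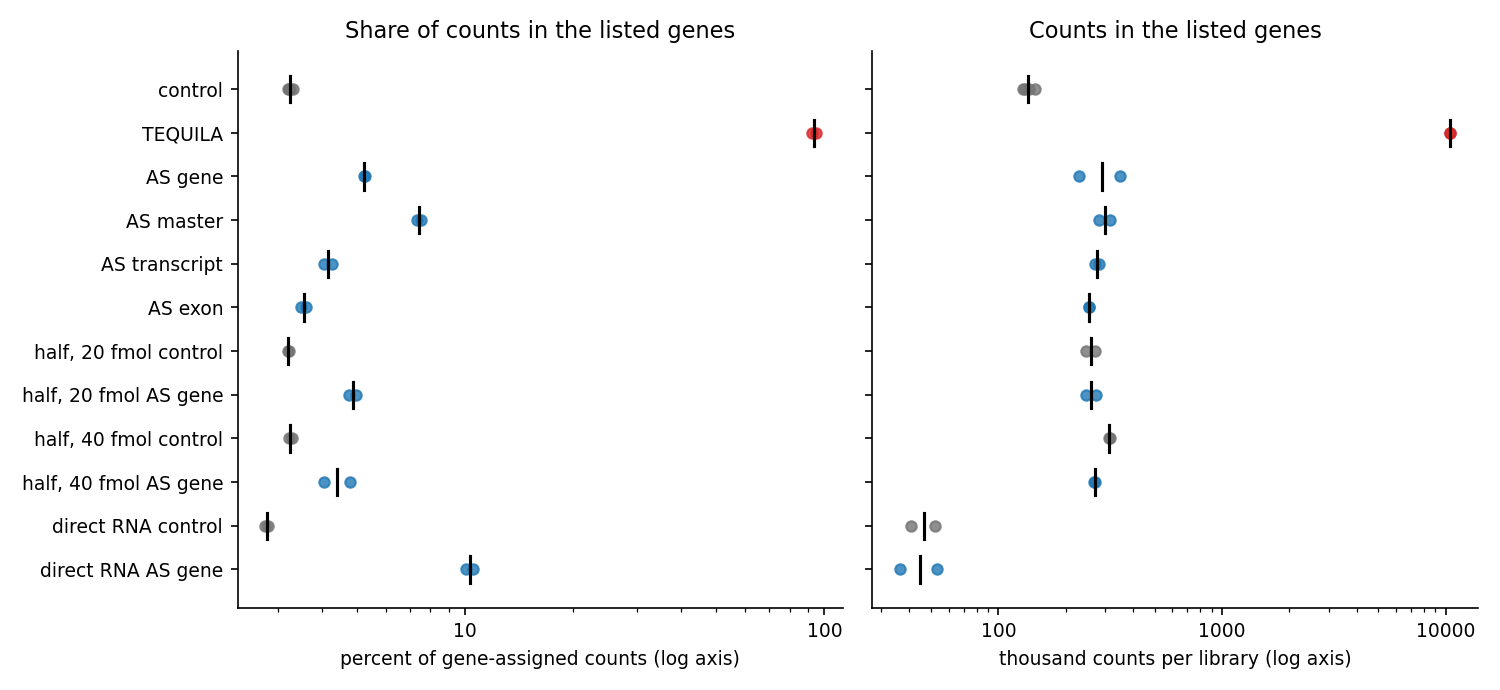
Each dot is 1 SH-SY5Y library of 12 groups and each black bar a group mean, on log axes, for the percent of gene-assigned counts in listed genes (left) and the counts in listed genes in k (right). TEQUILA libraries sit near 93.3%, direct RNA libraries with adaptive sampling near 10.3%, and cDNA controls near 3.25%.

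TEQUILA raised nearly every splicing factor on the target list far above the control level. Of 275 listed genes, 252 were higher and 8 lower, with a median log2 fold of 8.66, and all 141 tested genes that are also on the splicing lists were higher. RBM4B (ENSG00000173914.12, GRCh38 11:66664998-66677887), an RNA-binding splicing regulator, went from 22.8 ± 2.01 CPM (SD, n = 4) to 27964 CPM (n = 2), a log2 fold of 10.25 ± 0.18 (SE, adjusted p = 2.3e-30). The neuronal regulator ELAVL4 (1:50048014-50203772) rose by 10.20 ± 0.19 (adjusted p = 9.9e-30) from 1.85 to 2250 CPM, and SRPK2, a kinase of SR proteins, by 10.06 ± 0.17 from 40.4 CPM. KHDRBS3 (8:135457456-135647610) had 0 counts in the 4 controls and 66.5 ± 0.707 counts, or 51.8 ± 14.5 CPM, with TEQUILA. All 14 SR proteins, 23 of 24 hnRNPs, all 25 tested tissue-regulated splicing factors and all 16 Sm and LSm proteins were higher, with median log2 folds of 8.81, 8.94, 9.23 and 7.35. U1 and U2 snRNP and 3′ splice site factors had 22 genes higher and 3 lower of 27 (median 8.76). Tri-snRNP and PRP19 complex proteins had 24 higher and 7 lower of 35 (8.12; 8 lower adjusted over the list alone), and other splicing RNA-binding proteins, helicases and kinases 26 higher and 7 lower of 43 (8.24; 27 higher adjusted over the list alone). These 7 lists hold the study's own targets, and each kept its camera call with an estimated correlation (adjusted p = 0.029). Exon junction complex and mRNA export genes, mostly unlisted, had 7 genes higher and 5 lower of 17 (median 0.13; 6 lower adjusted over the list alone; adjusted p = 0.11 by camera).

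Some listed genes were not captured. CBX3 (7:26201162-26213607), a chromatin protein whose gene adjoins HNRNPA2B1, fell by 1.26 ± 0.11 (adjusted p = 3.7e-11), to 154 CPM from 370 and EIF2S2 fell by 0.78 ± 0.17 (adjusted p = 0.00043). Among the largest rises of unlisted genes, CELF3 (1:151700058-151716803) went from 0.0465 to 258 CPM (log2 fold 11.89 ± 0.36). CELF3 is on the fixed list of tissue-regulated factors, and the sources used here do not say whether it had probes. The pseudogenes HNRNPCP4 and HNRNPA1P59, also among these rises, were at 0 counts in the controls. Reads of a close paralog or pseudogene may be assigned to either copy, so these rises are uncertain. Of 13921 unlisted genes, 2569 were higher and 2764 lower. TMM puts the median gene at no change, whereas with library totals the median log2 fold of all genes was -3.45 and 90 unlisted genes were higher and 13540 lower. Cytosolic ribosomal protein genes, all unlisted, were lower in 76 of 76 (median log2 fold -1.68, adjusted p = 0.1 with an estimated correlation). Noradrenergic markers had 4 of 12 lower (median -0.59) and breast epithelial markers 8 of 12 (median -0.69). Mesenchymal markers had 6 of 12 higher (9 adjusted over the list alone) at a median of 0.56, which lies below 0 with library totals. The 7 synaptic genes had a median of 0.19 and a mean of -0.09, with 1 higher.

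**Figure D2:**
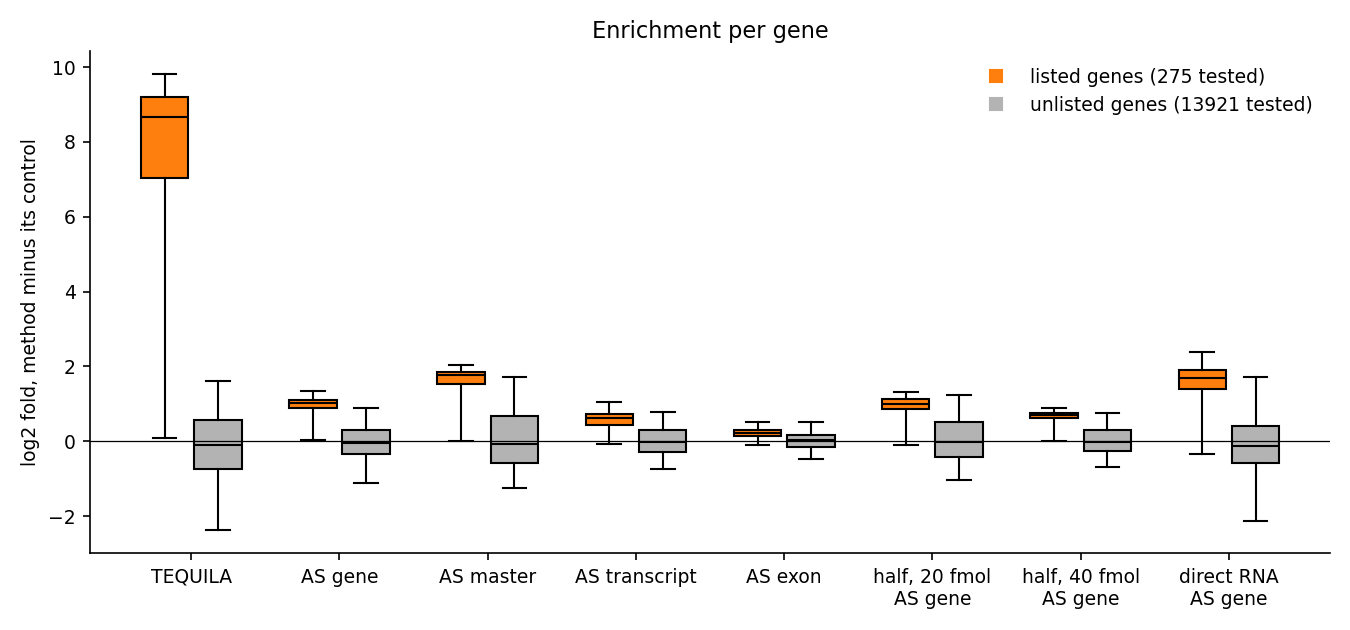
Boxes give the log2 folds of 275 listed (orange) and 13921 unlisted (grey) genes in 8 contrasts of SH-SY5Y libraries, with quartiles, the median as a line and whiskers from the 5th to the 95th percentile. Listed medians run from 0.22 for the exon-based design to 8.66 for TEQUILA.

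Gene-based adaptive sampling roughly doubled splicing-factor counts relative to other genes. SNRNP35, a protein of the minor spliceosome (ENSG00000184209.15, 12:123458088-123473154), rose from 17.6 ± 1.36 to 44.7 ± 3.58 CPM (log2 fold 1.35 ± 0.16, adjusted p = 4e-07). HNRNPH2 (X:101408222-101414133) rose from 37.7 ± 4.06 to 90.1 ± 0.255 CPM (1.25 ± 0.15, adjusted p = 4.8e-07) and the splicing-factor kinase UHMK1 from 23.4 ± 3.35 to 56.1 ± 1.70 CPM (1.25 ± 0.16). Of 275 listed genes 216 were higher and 2 lower, at a median log2 fold of 1.03, and 134 of the 141 on the splicing lists were higher. The lower genes were ENOPH1 (-0.36 ± 0.14) and RPL5P1 (-1.57 ± 0.21), the latter a ribosomal pseudogene whose reads are uncertain. Higher genes numbered 13 of 14 SR proteins (median 1.07), 23 of 24 hnRNPs (1.06), 18 of 25 tissue-regulated factors (1.06; 19 adjusted over the list alone), 26 of 27 U1, U2 and 3′ splice site factors (1.03), 25 of 35 tri-snRNP and PRP19 complex proteins (0.94; 26 adjusted over the list alone), 15 of 16 Sm and LSm proteins (1.00), 25 of 43 other splicing RNA-binding proteins, helicases and kinases (0.88) and 5 of 17 exon junction and mRNA export genes (0.20; 6 adjusted over the list alone). With an estimated correlation none of these lists was called, the lowest being adjusted p = 0.086 for U1, U2 and 3′ splice site factors.

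Unlisted genes also moved with the gene-based design, with 1821 higher and 1652 lower. Leaving out replicate 1 or 2 of the gene-based libraries reduced those 3473 calls to 1840 and 2040. Library totals put the median of all genes at -0.34 and gave 630 unlisted genes higher and 4492 lower. Cytosolic ribosomal proteins were higher in 63 of 76 genes at a median log2 fold of 0.77 (65 adjusted over the list alone), a camera call at adjusted p = 8.1e-35 that became adjusted p = 0.15 with an estimated correlation. Control replicate 2 stands apart by 0.41 in the same ribosomal genes, with 74 of 76 above the other controls. The medians of the other controls, each against the mean of the rest and so lowered by replicate 2, ran from -0.21 to -0.04. Noradrenergic markers, which mark the sympathetic identity of SH-SY5Y, had 1 of 12 higher and 4 lower (median -0.40), mesenchymal markers 3 of 12 lower (-0.18) and breast epithelial markers 3 of 12 lower (-0.15). The 7 synaptic genes had a median of 0.08 and a mean of -0.04, with none called. Among single unlisted genes, the metallothionein MT1A rose from 0.201 to 1.48 CPM (2.85 ± 0.70, adjusted p = 0.0026), and AHRR had 7.25 counts in the controls and 0 in the gene-based libraries.

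The master-based design gave larger folds than the gene-based one, and the exon-based design gave almost none. With the master-based reference, BICC1 (10:58512872-58831435) rose from 5.98 ± 1.22 to 24.9 ± 1.48 CPM (2.07 ± 0.23, adjusted p = 1e-08), RBM33 from 26.9 to 110 CPM (2.04 ± 0.15, adjusted p = 4.5e-12) and U2AF1L4 from 0.475 to 3.18 CPM (2.74 ± 0.53). In all, 234 listed genes were higher and 6 lower (median 1.77), while ARL6IP6 fell by 1.03 ± 0.19 (adjusted p = 3.2e-05). The median log2 folds were 1.80 in SR proteins, 1.83 in hnRNPs, 1.76 in Sm and LSm proteins and 1.02 in ribosomal proteins (52 of 76 higher, 10 lower). Unlisted genes numbered 3640 higher and 3681 lower, against 4186 and 2741 with RLE scaling and 1867 and 6611 with library totals (median of all genes -0.59). Directly compared, 202 listed genes were higher and 7 lower with the master-based than the gene-based reference, among them U2AF1L4 (1.29 ± 0.49, adjusted p = 0.047), whereas ABHD14B was lower (-0.83 ± 0.13, adjusted p = 2.8e-05, 53.5 against 95.1 CPM). Unlisted genes between this pair were 2160 higher and 1612 lower, 2700 and 983 with RLE, and 1082 and 2629 with library totals (median -0.18). Without gene-based replicate 1, master-based replicate 1 or master-based replicate 2 the 3772 calls became 2225, 2257 and 2420.

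The transcript-based design raised PCBP3 from 5.16 to 12.5 CPM (1.28 ± 0.23, adjusted p = 0.00021), the epithelial splicing regulator ESRP2 from 30.2 to 64.4 CPM (1.10 ± 0.16) and RALY from 81.8 to 170 CPM (1.05 ± 0.13). It gave 193 listed genes higher and 1 lower (median 0.61), or 92 higher without its replicate 2. Ribosomal proteins were higher in 64 of 76 (median 0.59, adjusted p = 0.15 with an estimated correlation). Its unlisted calls were 1686 higher and 1231 lower, a total of 2917 that became 1819 and 983 without its replicate 1 or 2, and with library totals they were 505 higher and 3388 lower (median of all genes -0.27). Compared with the gene-based design, HNRNPH1 (-0.77 ± 0.16, adjusted p = 0.003, 152 against 260 CPM), HNRNPH2 (-0.79 ± 0.18) and PRPF38A (-0.89 ± 0.18) were among 31 listed genes lower, with 2 higher (median -0.38). That 31 became 2, 3, 0 and 4 without gene-based replicate 1 or 2 or transcript-based replicate 1 or 2, and the 578 unlisted calls (468 higher, 110 lower; 349 and 32 with library totals) became 182, 238, 224 and 283.

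No gene was called by edgeR for the exon-based design against control, with 1294 genes at unadjusted p under 0.05 and a listed median of 0.22. DESeq2 called 43 unlisted genes higher and 13 lower. A fit without control replicate 2 and the 40 fmol gene-based replicate 2, chosen only after the result was seen, had 8 listed genes higher and 1 lower and 432 and 185 unlisted. No gene of the SR, hnRNP or ribosomal lists was called, and adjusted over the list alone 1 exon junction or mRNA export gene was higher and 1 breast epithelial marker lower. Leaving out control replicate 2 or exon-based replicate 1 gave 4 and 5 unlisted calls. Against the gene-based design, the exon-based one was lower in 201 listed genes and higher in 2 (median -0.79), for example in ABHD14B (-1.12 ± 0.12, adjusted p = 4.7e-08) and in all but 1 of the 14 SR proteins. Unlisted genes were 1261 higher and 1067 lower there, but 2282 and 332 with library totals (median of all genes 0.25), and the 2328 calls became 1179, 1251 and 1165 without gene-based replicate 1, gene-based replicate 2 or exon-based replicate 2. TEQUILA against the gene-based design had 242 listed genes higher and 9 lower (median 7.66), such as SRPK2 (9.08 ± 0.23, adjusted p = 1.9e-25), while ELOB was lower (-1.62 ± 0.17, adjusted p = 1.3e-09, 394 against 1212 CPM) as were 76 of 76 ribosomal proteins (median -2.38). Its unlisted genes were 2563 higher and 2604 lower, or 94 and 13093 with library totals (median -3.09).

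At a load of 20 fmol on the half-flow-cell runs, gene-based sampling again raised the splicing factors, and ribosomal proteins were higher too. RAVER2 (1:64745075-64833232), a PTB-binding protein, went from 3.38 to 8.80 CPM (1.37 ± 0.34, adjusted p = 0.0016). SR proteins had a median log2 fold of 0.99, hnRNPs 1.00, Sm and LSm proteins 1.18 and ribosomal proteins 1.05, with 68 of 76 ribosomal genes higher (adjusted p = 0.16 with an estimated correlation). In all 225 listed genes were higher and 3 lower (median 0.99), the lower ones being ARL6IP6 (-0.61 ± 0.17), ENOPH1 (-0.54 ± 0.15) and MRRF (-0.44 ± 0.16). Unlisted calls were 2925 higher and 2619 lower, 3434 in sum without the 20 fmol gene-based replicate 1, and 1165 higher and 5581 lower with library totals (median of all genes -0.43). The share of listed genes was 4.86% ± 0.146 against 3.22% ± 0.0127, and the yield 259.9 k ± 18.8 against 258.4 k ± 16.1 (SD, n = 2 each), where 6 splits allow no p under 0.333.

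At 40 fmol splicing factors rose too, with calls that rested on 1 library. ELAVL1 (19:7958573-8005659) rose to 48.5 ± 5.40 CPM (0.90 ± 0.17, adjusted p = 0.0013), MSI2 by 0.89 ± 0.18 and SCAF1 by 1.13 ± 0.25, and 197 listed genes were higher with none lower (median 0.70). Medians were 0.72 in SR proteins, 0.71 in hnRNPs and 0.67 in ribosomal proteins (62 of 76 higher). Unlisted calls were 1386 higher and 891 lower, and 288 and 2466 with library totals (median -0.26). Without gene-based replicate 1 there were 0 listed calls and 3 unlisted, and without control replicate 1 there were 107 and 920; without control replicate 2 the unlisted calls were 1338. With only these 4 libraries fitted no gene was called, at a like listed median of 0.70. The shares were 4.76% and 4.03% against 3.25% ± 0.0392 and the yield 270.1 k ± 2.11 against 313.9 k ± 1.26. The effect at 40 fmol was not different from that at 20 fmol in any gene by edgeR, with 1193 genes at unadjusted p under 0.05 and a listed median difference of -0.30 (median of all genes 0.16 with library totals), although without the 40 fmol gene-based replicate 1 there were 2 listed and 197 unlisted calls and without control replicate 1 at 40 fmol 22 unlisted. DESeq2 called no gene in this difference either.

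In direct RNA, which sequences native molecules without amplification, gene-based sampling gave the largest share gain of the adaptive runs. The RNA-binding protein TIA1 (2:70209444-70248660) rose from 20.5 ± 3.18 to 111 ± 26.5 CPM (2.39 ± 0.27, adjusted p = 4.9e-08) and LSM10 (1:36391238-36397908), of the U7 snRNP, from 19.4 ± 0.212 to 91.6 ± 7.43 CPM (adjusted p = 1.5e-07). RBM12 rose by 3.45 ± 0.59, though from 4.5 counts to 15.0. Of the listed genes 199 were higher and 5 lower (median 1.70), with NDUFB11 (-1.41 ± 0.19, adjusted p = 1.5e-06, 274 to 102 CPM), DYNLL1 (-0.70 ± 0.13) and JAK1 (-0.83 ± 0.20) lower. Higher were 13 SR proteins (median 1.82), 22 hnRNPs (1.69) and 15 Sm and LSm proteins (1.98; 16 adjusted over the list alone), of which the last kept its call with an estimated correlation (adjusted p = 0.042). Ribosomal proteins went the other way, with 51 of 76 lower and 10 higher (median -0.60; 55 lower adjusted over the list alone; adjusted p = 0.26 with an estimated correlation). The share rose from 2.80% ± 0.0400 to 10.3% ± 0.312, a ratio of 3.67, but the yield was 44.8 k ± 12.1 against 46.6 k ± 8.06, because total counts fell from 1.49 M and 1.87 M to 0.351 M and 0.539 M. The yield difference of -1.71 k became 3.98 k without control replicate 2 and 6.87 k without gene-based replicate 1. Unlisted calls were 569 higher and 1323 lower, against 693 and 861 with RLE and 692 and 477 with library totals, and the sum of 1892 became 1218 and 1045 without gene-based replicate 1 or 2.

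The effect in direct RNA exceeded the half-flow-cell cDNA effect in 131 listed genes and was below it in 5, at a median difference of 0.85. SNRNP48 (1.66 ± 0.47) and RBM12 (2.59 ± 0.61, adjusted p = 0.0027) were among the highest, and NDUFB11 (-2.24 ± 0.21, adjusted p = 4.3e-09) and DYNLL1 (-1.38 ± 0.15) the lowest. Ribosomal proteins went down, with 61 of 76 lower and 4 higher (median -1.37, adjusted p = 0.1 with an estimated correlation), against 13 of 14 SR proteins higher (0.96). Unlisted genes were 506 higher and 1333 lower, but 1528 and 392 with library totals (median of all genes 0.44). Without direct RNA gene-based replicate 1 or 2 the 131 became 80 and 86, and without replicate 2 the 1839 unlisted calls became 1149.

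The control libraries themselves differed widely between direct RNA and cDNA. HNRNPK (9:83968083-83980630), an abundant hnRNP, had 488 ± 18.2 CPM in cDNA and 5.77 ± 0.291 in direct RNA (-6.39 ± 0.26, adjusted p = 1.7e-19), a gap in which a difference in read assignment between library types was not tested, and MEX3D (19:1554672-1568325) had 0.228 ± 0.0930 and 31.3 ± 1.36 (6.99 ± 0.34, adjusted p = 1.6e-17). KHSRP (2.86 ± 0.21), SART1 (3.81 ± 0.19) and HNRNPAB (2.66 ± 0.14) were higher in direct RNA. TMEM238 (19:55379244-55384292) had 512 ± 10.1 CPM in direct RNA and 2.45 ± 0.803 in cDNA (7.74 ± 0.14), and the histone gene H1-3 had 0 counts in direct RNA and 2163 in cDNA. Pseudogenes such as RPL13AP7 (10.45 ± 0.15) and PTENP1 were among the highest and are uncertain. In all, 53 listed genes were higher and 107 lower, and 3544 and 4146 unlisted. The hnRNPs divided into 10 higher and 8 lower, and tissue-regulated factors were lower in 12 and higher in 3 (median -1.12). Ribosomal proteins had 28 higher and 14 lower, with a median of 0.18 and a mean of -0.14.

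Short unlisted transcripts rose with adaptive sampling of cDNA. In the shortest decile of unlisted genes, with a median length of 577 b, the median log2 fold was 1.24 for the master-based, 0.52 for the gene-based and 0.48 for the transcript-based design, and -0.34 for TEQUILA. With the master-based design 891 of 1390 genes of that decile were higher (64.1%) and 43 lower. Within it the 37 ribosomal genes had a median of 0.81 for the gene-based design against 0.50 for the other 1353, and with the master-based design 1.11 against 1.25, so the rise was not confined to ribosomal genes. With the exon-based design these medians were only 0.16 and 0.14. In direct RNA the decile did not rise, with medians of -0.66 in ribosomal and 0 in the other genes. The gap between the shortest and longest quartile was 0.33 for the gene-based (95% interval over genes 0.30 to 0.36), 0.67 for the master-based (0.59 to 0.73), 0.32 for the transcript-based (0.30 to 0.35) and 0.15 for the exon-based design (0.13 to 0.16). It was 0.75 (0.70 to 0.79) at 20 fmol, 0.40 (0.38 to 0.43) at 40 fmol, 0.14 (0.11 to 0.17) in direct RNA and 0.06 (-0.002 to 0.11) for TEQUILA. These intervals cover the spread over genes only. Control replicate 2 had a gap of 0.14 to the other controls over 5557 genes and control replicate 4 one of -0.14, so a gap near the exon-based size also arises between single controls. Each was compared with the mean of the other controls, so these 2 values are not independent. Among 273 listed genes, Spearman's rho between log2 fold and length, across genes that are not independent replicates, was 0.255 for TEQUILA, 0.173 for gene-based, 0.191 for master-based, 0.0390 for transcript-based, 0.138 for exon-based, -0.0640 at 20 fmol, 0.0178 at 40 fmol and -0.077 in direct RNA.

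**Figure D3:**
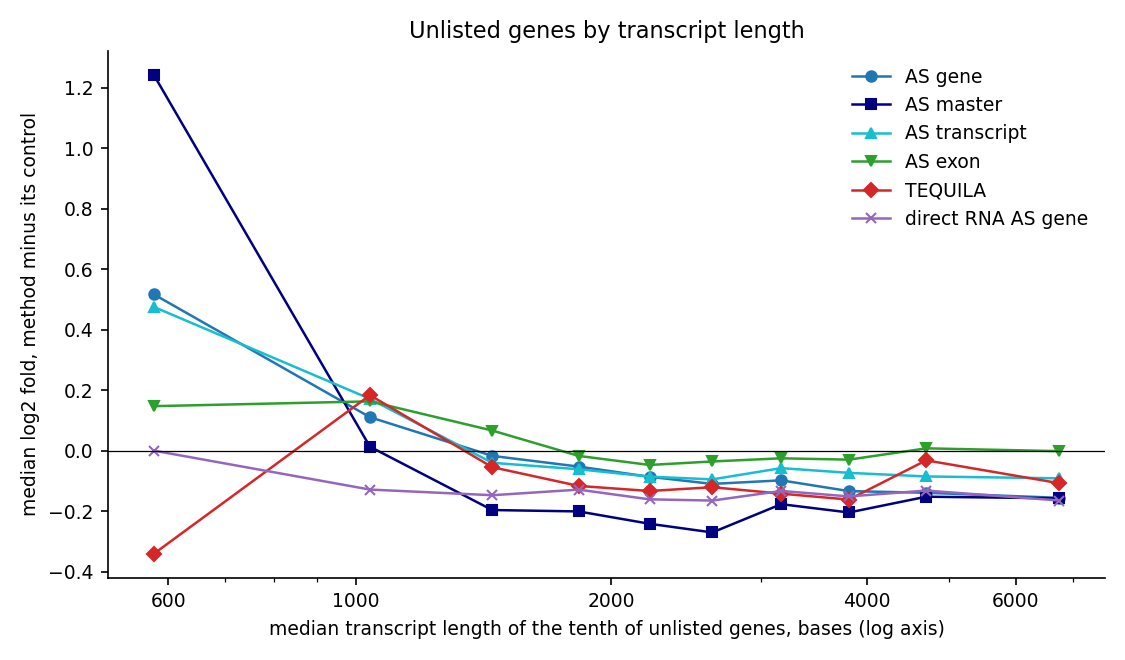
Lines give the median log2 fold of unlisted genes in each decile of transcript length (log axis, in bases) for 6 methods against their controls. In the shortest decile the medians are 1.24 for the master-based and 0.52 for the gene-based design and -0.34 for TEQUILA.

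Unlisted genes that overlap a listed gene on either strand were tested for spill-over. With the gene-based design 5 of 28 such genes were higher (17.9%) against 1816 of 13893 others (13.1%), an odds ratio of 1.45 (Fisher's exact test, two-sided, p = 0.403, adjusted p = 0.645). With TEQUILA 10 of 28 were higher, an odds ratio of 2.46 (exact p = 0.0266, adjusted p = 0.213). On the same strand there were 6 overlapping genes, 3 of them higher with the gene-based design (odds ratio 6.65, exact p = 0.0329, adjusted p = 0.0658) and 4 with TEQUILA (8.85). These counts leave out neighbours that are themselves listed, such as COX20, which overlaps HNRNPU, so they cannot show spill-over onto those genes. Overlap with targets on the splicing lists, listed neighbours included, was added after the result was seen. With the gene-based design 18 of 47 such genes were higher (38.3%) against 13.5% of others (odds ratio 3.99, Fisher's exact p = 1.97e-05, adjusted p = 7.89e-05).

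The spike-ins, synthetic RNAs of known length, divided by whether TEQUILA raised them by a log2 fold over 5. That limit, the length limit of 600 b and the minimum mean of 50 counts over the main cDNA controls were chosen after the values were seen. No minimum was set on direct RNA counts, where controls held a mean of 7452 spike-in counts, 7.42% of them ERCC. The sources used here do not say which spike-ins had probes or were in the sampling references, so this division need not mark targets. The 11 ERCC spike-ins so raised, 489 to 1108 b long, had a median log2 fold of 1.04 with gene-based, 1.79 with master-based, 0.40 with transcript-based and 0.15 with exon-based sampling, and 1.89 in direct RNA. The 5 long SIRVs so raised, 4001 to 12000 b, had 1.07, 1.83, 0.37, 0.29 and 2.11. ERCC spike-ins not raised by TEQUILA parted by length. The 3 under 600 b (ERCC-00046, ERCC-00074 and ERCC-00162, 506 to 507 b) rose by 0.84 with gene-based and 1.51 with master-based sampling but changed by -0.06 in direct RNA, and the 8 longer ones changed by 0.06, -0.04 and -0.21. The 10 long SIRVs not raised by TEQUILA fell, with medians of -0.28, -0.52 and -1.71 in the same order, except SIRV10001 (0.68) and SIRV10003 (0.34) with gene-based sampling. The SIRV isoform mix moved alike whether TEQUILA had raised it or not, with medians of 0.54 and 0.47 for the gene-based design. Direct RNA libraries with adaptive sampling held only 1086 and 1697 spike-in counts.

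**Figure D4:**
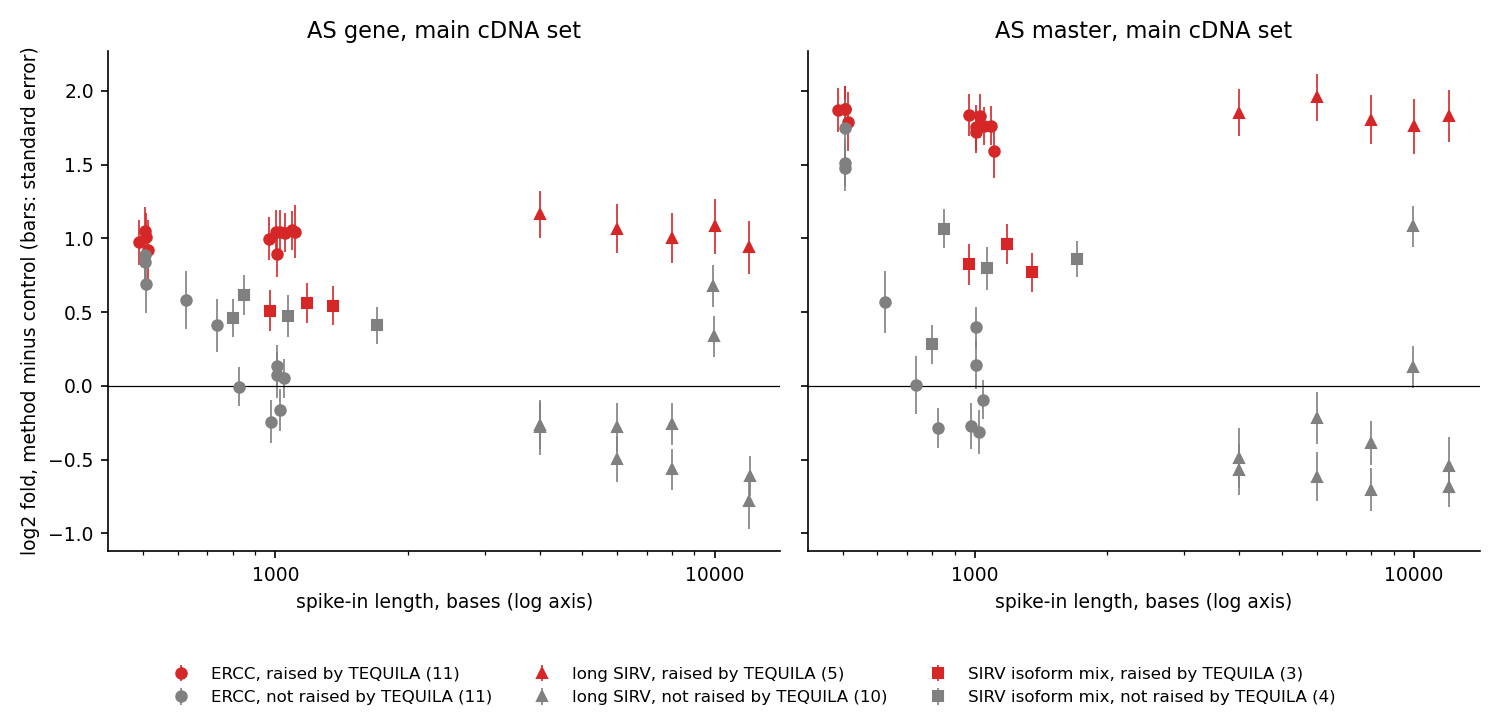
Points give log2 folds with SE of single spike-ins against length in bases (log axis) for gene-based and master-based sampling, red where TEQUILA raised the spike-in and grey where it did not, with circles for ERCC, triangles for long SIRVs and squares for the SIRV isoform mix. Grey circles under 600 b lie near 0.84 and 1.51, and longer grey circles near 0.06 and -0.04.

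Isoform usage, the question for splicing, changed in few listed genes with adaptive sampling. Of 211 genes, edgeR's gene-level test called 2 for the gene-based design (SNRPC and RBMS2), 11 for the master-based, 1 for the transcript-based (CWC22) and 3 for the exon-based design (SREK1, BUD13 and CWC22), and 34 for TEQUILA. The Simes test gave 0, 8, 3, 5 and 18. Of the 211 genes, 128 are on the fixed splicing lists. By the gene-level test these made up 1 of the gene-based, 3 of the master-based and 19 of the TEQUILA calls. They made up 0 of the transcript-based and exon-based calls and 6 of those in direct RNA. SNRPC-201 went from 91.4% to 95.1% of its gene's counts with gene-based sampling (adjusted p = 0.000433). With TEQUILA, HNRNPA1-203 (12:54280193-54287087) went from 84.5% ± 0.331 to 73.9% ± 0.0264 and HNRNPA1-202 from 4.43% ± 0.0892 to 13.0% ± 0.146 (adjusted p = 7.49e-54). The single-exon SRSF9-203 went from 46.4% ± 4.81 to 2.49% ± 0.574 while SRSF9-201 went from 44.2% ± 4.68 to 84.6% ± 0.772 (adjusted p = 6.30e-25). HNRNPU-219 went from 12.5% ± 1.72 to 2.81% and HNRNPU-205 from 62.5% to 71.0% (adjusted p = 1.96e-15). With the master-based design 2 single-exon transcripts gained share, DYNLL1-210 from 3.22% ± 0.614 to 8.96% ± 0.845 (adjusted p = 2.24e-07) and NFE2L3-202 from 48.7% ± 7.30 to 84.1% ± 6.32 (adjusted p = 7.26e-06). DYNLL1 and NFE2L3 are listed neighbours of SRSF9 and HNRNPA2B1 and are not on the splicing lists. DYNLL1-210 also gained in direct RNA, from 4.02% ± 0.135 to 15.1% ± 1.64 (adjusted p = 3.12e-09), among 12 genes called there, or 3 by the Simes test. In CWC22 an unannotated transcript of 3164 b went from 49.5% ± 34.7, a share that varied between control libraries, to 0%. The annotated CWC22-201 gained with the transcript-based design, from 26.4% to 45.9%, and another unannotated transcript of 3174 b with the exon-based design. No gene was called at 20 fmol, where 20 had unadjusted p under 0.05 and the Simes test called 2, and 1 gene, CWC22, at 40 fmol.

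Single libraries decided several of these counts. The TEQUILA count of 34 became 21 without either TEQUILA library, and the gene-based 2 became 0 or 1 without its replicate 1 or 2. The master-based 11 became 7 without control replicate 4 and 6 or 5 without master-based replicate 1 or 2. The transcript-based 1 became 6 without control replicate 1 and 0 without control replicate 2, control replicate 3 or transcript-based replicate 1, and the exon-based 3 became 0 without its replicate 2. At 20 fmol 2 genes appeared without control replicate 1, at 40 fmol 8 without control replicate 1 and 0 without gene-based replicate 1, and in direct RNA the 12 became 7 without control replicate 2 and 4 without gene-based replicate 2.

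Direct RNA and cDNA controls differed in isoform usage in 139 of 211 genes (65.9%), or 90 by the Simes test and 90 without direct RNA control replicate 2. TRA2B-204, the main TRA2B transcript, took 71.5% in direct RNA and 41.7% in cDNA, and TRA2B-212 took 0.123% ± 0.174 and 35.0% ± 1.66 (adjusted p = 1.32e-60). LSM7-204 took 64.1% ± 0.261 and 9.93% ± 1.35 (adjusted p = 8.03e-40). Per gene, the absolute share changes were summed over transcripts and divided by 2, without thinning to a common depth. The median over the 211 genes was 14.2 percentage points here, 4.77 for TEQUILA and 4.04 for the gene-based design.

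In the main cDNA set, isoform shares of listed genes thinned to 50 counts were no farther between adaptive sampling and control libraries than within groups. In these 193 genes the mean distance between isoform shares was 19.1% between control libraries and 20.8% between TEQUILA and control, an excess over the distance within groups of 1.89 (one-sided exact permutation test, p = 0.0667, the smallest of 15 splits). The excess was -0.60 for gene-based (exact p = 0.933), -0.21 for master-based (exact p = 0.867), -0.15 for transcript-based (exact p = 0.8) and -0.33 for exon-based sampling (exact p = 0.933). It was 0.33 at 20 fmol (exact p = 0.333, the smallest of 6 splits), -0.21 at 40 fmol and 0.050 in direct RNA, and at 100 counts 0.247, 0.545 and 0.409 in that order. In the main set at 100 counts it was 0.0259 for gene-based, -0.00639 for master-based, 0.0914 for transcript-based and 0.113 for exon-based sampling (exact p from 0.267 to 0.533). Differences under the noise of 50 counts were not detectable at this depth.

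TEQUILA detected the most isoforms of listed genes at the depths as sequenced. At 3 or more counts, 14853 ± 215 isoforms were found with TEQUILA, of which 13114.5 were not annotated, against 1911.5 ± 62.7 in controls, 2788 ± 406 with gene-based and 2825 ± 170 with master-based sampling. Spike-ins have known structures, yet TEQUILA libraries had a mean of 149 unannotated spike-in transcripts at that minimum, beside 151.5 annotated. Controls had 5.5 and gene-based libraries 6.5. They held 0.207% of spike-in counts with TEQUILA and 0.174% in controls, and TEQUILA had more spike-in counts. Unannotated isoforms of listed genes may thus include false ones. Thinned to 128734 listed counts per library the controls had 1859.75 ± 47.1, gene-based libraries 1825.5 ± 12.0, master-based 1814.5, transcript-based 1811.5 and exon-based 1871.5. TEQUILA libraries thinned alike had 1899 and 1941 (exact two-sided permutation, p = 0.267), where 15 splits allow no p under 0.0667. At 20 fmol the thinned counts were 2656.5 with gene-based sampling and 2743.5 without, at 40 fmol 2667 and 2687, and in direct RNA 737 and 761.

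Pooled SH-SY5Y columns, which hold listed genes only and have 47.2 k to 62.3 k counts, gave the relative abundance among targets. Gene-based sampling kept all 147 genes with at least 100 counts within 2-fold of the control share (Spearman's rho 0.989 across genes), and master-based sampling all 151 (0.990). TEQUILA kept 116 of 166 (0.718). RBM33 took 4.81 times its control share with TEQUILA (95% interval 3.32 to 7.18), SNRNP35 4.32 times (2.78 to 6.97) and SRPK2 3.45 times. Sm and LSm proteins, whose transcripts are short, had a median ratio of 0.383 with 12 of 15 below 1, lower than all 10000 random lists, and SNRPF took 0.115 of its control share. Tissue-regulated factors had a median ratio of 1.89 over 11 genes (percentile 94.6 of random lists), but genes enter by the counts of both columns, so some enter through TEQUILA's own counts. ELOB had 2 counts with TEQUILA and 1325 in the control, and COX20 5 and 599. In direct RNA 140 of 141 genes stayed within 2-fold under gene-based sampling, the exception being JAK1 at 0.136 (0.0781 to 0.222). Direct RNA and cDNA controls ranked the genes less alike (rho 0.628), and the hnRNPs divided, with 14 of 23 above their cDNA share and 9 below (HNRNPK 0.0129). Their median ratio of 1.46 lay at percentile 99.9 of random lists, against 1.12 for all genes. At least 3 counts were held by 814 isoforms in the control, 954 with TEQUILA, 857 with gene-based and 843 with master-based sampling. The TEQUILA column is also the deepest, with 62.3 k counts against 47.7 k in the control, and at 1 count its ratio to the control was 1.02.

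The breast cancer lines were sequenced with a panel of 468 cancer genes. The on-target columns held 712 genes in BT549 and 670 in T47D, more than the panel. Panel membership of single genes was not checked here, so the TEQUILA ratios and the counts within 2-fold below may include genes without probes. Under TEQUILA the growth-factor receptor gene IGF1R took 11.7 times its control share in BT549 (8.02 to 17.5) and 17.3 times in T47D (14.7 to 20.7), ABL1 12.7 times in T47D, and VEGFA 7.44 times in BT549 and 8.66 times in T47D. No test compared the fixed lists between the 2 lines, and their members with enough counts differ. Luminal and hormone receptor genes had a median ratio of 3.11 in BT549 and 1.39 in T47D (percentile 49.8 of random lists), over 7 and 12 genes. Some of these enter through TEQUILA's own counts, since with at least 100 counts in the control column alone the T47D ratio was 1.15 over 8 genes and BT549 had fewer than 5. The ratios were, for receptor tyrosine kinases with mesenchymal-associated genes, 1.10 (32.5) and 2.82 (98.9) over 10 and 8 genes, and by the control column alone 0.842 and 2.69 over 6 and 7. Homologous recombination genes had 1.87 and 2.03, RAS-MAPK genes 1.78 and 1.95, and mismatch repair genes 1.02 and 0.781, against 1.33 and 1.39 for all genes. Genes such as AP1S2 (1 count with TEQUILA against 680 in BT549, 0 against 1007 in T47D) and SLC35F6 (4 against 1444 in BT549) were nearly absent with TEQUILA. Whether these genes had probes was not checked. The 5 breast epithelial markers with enough counts in T47D had 0.967. Gene-based sampling left 373 of 380 genes within 2-fold in BT549 (rho 0.991) and 377 of 387 in T47D (0.986), and master-based 364 of 380 (0.985) and 364 of 384 (0.980), while TEQUILA left 204 of 379 (0.724) and 194 of 385 (0.70). Largest falls with gene-based sampling were in RPL4P4, a pseudogene and so uncertain (0.273 in BT549), RFC4 (0.387) and LRRC41 (0.425). Isoforms with at least 3 counts numbered 3919 in the BT549 control, 3919 with TEQUILA, 3823 with gene-based and 3786 with master-based sampling, and 3603, 3532, 3529 and 3480 in T47D. The TEQUILA ratio to the control at 1, 3 and 10 counts was 0.879, 1.00 and 1.08 in BT549 and 0.872, 0.980 and 1.07 in T47D, so its side depends on the minimum.

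The control columns separated the basal-like, mesenchymal line BT549 from the luminal line T47D. EPCAM, an epithelial adhesion gene, had 0 counts in BT549 and 5673 in T47D, at least 2361-fold, and CDH1, which encodes E-cadherin, 10 and 2575, or 322-fold (175 to 671). SOX2 had 0 and 387 counts. The receptor kinase DDR2 had 516 counts in BT549 and 0 in T47D, at least 138-fold, MET 2471 and 3 (660-fold, 225 to 3201), and CDK6 was 21.8-fold higher in BT549 (12.0 to 44.1). Luminal and hormone receptor genes had a median log2 difference (BT549 minus T47D) of -3.99 over 8 of the list's 13 genes, 6 of them higher in T47D and SPEN and TBX3 higher in BT549, below all random lists, and cell cycle genes 0.64 over 20 genes (percentile 99.4). PI3K-AKT-mTOR genes had -0.59, RAS-MAPK genes -0.29, mismatch repair genes, a list that includes EPCAM, -0.40, receptor tyrosine kinases with mesenchymal-associated genes -0.27, homologous recombination genes -0.06 and chromatin regulators -0.02, all within the range of random lists. The luminal median was -4.06 with gene-based sampling, -4.12 with master-based and -2.64 with TEQUILA.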

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

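The tests of shorter molecules, of partial loss of rejection and of a wrong label were chosen only after the result was seen. So were the classes of spike-ins and the comparisons of single libraries with other controls. Overlap with targets on the splicing lists was also added then, and the percent of higher genes overlapping was not the planned measure. The interaction, the rho with length, the odds ratio for overlap and the length gap were planned.

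Control replicate 2 of the main cDNA set stood far from the other 3 controls in the spike-in isoforms of the SIRV mix. Their levels had a coefficient of variation of 0.842 against 0.686 to 0.703, and their rho with length was -0.556 against -0.325 to -0.305. Of 11 measures compared among the controls these 2 stood out, where chance alone marks about 1 in 20 groups for each measure. Over 11 measures a mark by chance is more likely than that, and these 2 come from the same spike-in isoforms. The same library was higher in 74 of 76 cytosolic ribosomal protein genes than the other controls, by a median log2 of 0.41. Control replicate 4 lay the other way, with 1 of 76 higher and a median of -0.21. Each control was compared with the mean of the other 3, so replicate 2 itself lowers that value and the sign is in part built in.

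The effect of gene-based sampling differed between direct RNA and half-flow-cell cDNA in a tested interaction. It was larger in 131 listed genes such as RBM12 and SNRNP48, and smaller in 5, among them NDUFB11 and DYNLL1. Of unlisted genes, 506 moved up and 1333 moved down in direct RNA relative to cDNA, the latter with 61 of 76 ribosomal proteins. With library totals the unlisted counts were 1528 and 392, so the direction among unlisted genes rests on the scaling, while the listed counts were 193 and 2. The libraries also differ in amplification and chemistry, and no biological explanation was tested, since every library is of 1 cell line.

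Listed genes gained unequally under gene-based sampling, from ELAVL4 and SNRNP35, which rose, to ENOPH1, which fell by 0.36. The pseudogene RPL5P1, whose reads are uncertain, fell further. Across genes the rho of log2 fold against transcript length was 0.173 (95% interval 0.0551 to 0.290). Length may carry a part of the difference, but this rho is too small to decide, and at 20 fmol it was -0.0640. Listed genes on the splicing lists were called higher more often than the other listed genes, among which are neighbours and pseudogenes. The sources used here do not say which listed genes were in the sampling references.

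Unlisted genes higher with the gene-based design, ribosomal proteins among them, were weighed against 3 technical explanations. Overlap with a listed gene is argued against as the main cause by number alone, since only 28 unlisted genes overlap one and 0.275% of the higher genes do. A set this small keeps that percent low in any case, so it does not test whether overlap raises a gene. Overlap may still add to single genes, since the odds ratio was 1.45 on either strand and 6.65 on the same strand (Fisher's exact p = 0.0329, adjusted p = 0.0658). The 3.99 for targets on the splicing lists counts listed genes beside a target as neighbours, so it does not bear on unlisted genes alone. Shorter molecules in the enriched libraries would raise short listed genes too, but the rho of 0.173 in listed genes of the main set has the opposite sign. With the same design it was -0.0640 (-0.188 to 0.0676) at 20 fmol and 0.0178 (-0.106 to 0.146) at 40 fmol. Shorter molecules are thus argued against in the main set only. Short molecules that finish before rejection stay open as an explanation. The shortest quartile of unlisted genes exceeded the longest by 0.3305 (0.301 to 0.364), but that gap is the pattern itself and does not decide its cause. The ERCC spike-ins not raised by TEQUILA had 0.84 under 600 b and 0.06 above, but only 3 of the shorter had enough counts, and the sources used here do not say which spike-ins were targets.

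At 40 fmol, gene-based replicate 2 gave less than replicate 1, with median log2 folds of 0.47 and 0.91 in listed genes and 0.40 and 0.88 in ribosomal proteins. A control under a wrong label is argued against, since its listed genes lay above its controls by 0.469 (0.461 to 0.486). Partial loss of rejection may explain it, because replicate 2 had 0.454 of replicate 1's length gap and 0.516 of its target gain, so both shrank nearly alike, with a difference of -0.0621 (-0.108 to -0.0149). Other run conditions of that library were not tested and stay open.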

How the results depend on the processing

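Values given for the fit without control replicate 2 and the 40 fmol gene-based replicate 2, and for pooled genes by their control column, were chosen only after the result was seen. Of 104 results with a comparison, 51 kept their direction and their side of the threshold under every alternative, and so did 534 of 686 alternatives, where a count within 1.5 times of its main value is taken as kept. RLE scaling moved none of 30 counts of listed or of all unlisted calls by over 1.5 times, but of the counts split by direction it moved 2, unlisted genes lower in direct RNA (1323 to 861) and in master-based minus gene-based (1612 to 983). The cause of a change was not tested unless its construction shows it, such as fewer samples or genes. Direct RNA had the smallest library, of 0.351 M counts.

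For share and yield, the half-flow-cell gain of 1.39 percentage points had p = 0.125 in an exact sign-flip test with replicates as a block. This is the smallest p that the sign-flip test allows, since the gene-based share was the higher in every pair. That test pairs libraries by number, although pairing by number was not established. The 20 fmol yield difference of 1.57 k became -14.0 k on the fixed splicing lists, and the direct RNA difference of -1.71 k became 1.24 k on listed genes of those lists. Leaving out single libraries gave 1.49 to 2.07 points for the 8 adaptive libraries, 1.28 to 1.59 for the half-flow-cell share, -11.7 k to 14.9 k for the 20 fmol yield and -10.3 k to 6.87 k for direct RNA.

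Among unlisted genes called, library totals gave 13630 for TEQUILA against 5333, 1169 for direct RNA against 1892, 13187 for TEQUILA minus gene-based against 5167 and 381 for transcript-based minus gene-based against 578. Each replicate block was fitted to the compared groups only, so it changes 2 choices against the full fit. It gave 2171 for gene-based (3473 in the full fit; 1679 higher and 1574 lower with those groups and no block), 1482 for transcript-based (2917; 1474 and 1268), 935 at 40 fmol (2277; 0), 3611 for exon-based minus gene-based (2328; 1802 and 1633), 2146 for transcript-based minus gene-based, 3 for exon-based and 1 for 40 minus 20 fmol. A crossed block gave 3773 for exon-based minus gene-based and, at 40 fmol, 208 listed genes higher and 1280 unlisted higher and 840 lower. With only the compared groups fitted and no block, transcript-based minus gene-based had 2007 unlisted calls and 165 listed genes lower (31 in the full fit; 170 with a block, 55 with library totals, 78 without a filter), and 40 fmol had 0 listed and 0 unlisted against 197 and 2277, at a listed median of 0.70. No filter gave 51 unlisted calls for 40 minus 20 fmol and, for the exon-based design, 3 listed and 14 unlisted; DESeq2 gave that design 56. Without control replicate 2 and the 40 fmol gene-based replicate 2, the exon-based design had 9 listed and 617 unlisted calls, 40 fmol had 3819 unlisted, and transcript-based minus gene-based had 84 listed lower and 1015 unlisted.

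Leaving out 1 library at a time, unlisted calls ran from 3735 to 5473 for TEQUILA, 1840 to 4192 for gene-based, 5600 to 7532 for master-based, 983 to 3830 for transcript-based, 0 to 5 for exon-based, 3434 to 4211 at 20 fmol, 3 to 3327 at 40 fmol and 1045 to 1525 in direct RNA. Between designs they ran from 2225 to 2662 for master-based, 182 to 283 for transcript-based, 1165 to 1616 for exon-based and 3930 to 4589 for TEQUILA, each minus gene-based. They ran from 0 to 197 for 40 minus 20 fmol, 1149 to 1984 for the direct RNA interaction and 5625 to 7464 between direct RNA and cDNA controls. Listed genes higher ran from 92 to 192 for transcript-based, 0 to 200 at 40 fmol and 80 to 141 for the interaction. Listed genes lower in transcript-based minus gene-based ran from 0 to 4, listed calls from 0 to 2 for 40 minus 20 fmol and from 120 to 157 between the controls. Leaving 1 library in a group assumes that it varies as the other groups do.

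Isoform usage calls for TEQUILA (34) were 18 by Simes, 27 with only the compared groups (177 genes tested) and 18 with a block on those groups; every later block is such a fit. For gene-based (2) they were 0 by Simes, 7 with annotated transcripts and 6 with only the compared groups, which gave 7 for master-based (11). Transcript-based (1) had 6 at a 5% share, 3 by Simes, 4 annotated, 2 with a block and 3 with only its groups, and exon-based (3) had 1, 5 by Simes and 1 with only its groups. At 20 fmol (0) there were 1 at a 5% share and 2 by Simes, and at 40 fmol (1) 2 by Simes, 2 annotated, 2 with a block and 2 with only its groups. Direct RNA (12) had 23 at a 5% share, 3 by Simes, 5 annotated, 1 with only its groups (105 genes tested) and 4 with a block on them, and the controls of direct RNA and cDNA (139) had 90 by Simes. Single libraries left out gave 21 to 32, 0 to 2, 5 to 13, 0 to 6 and 0 to 4 for the main set in that order, 0 to 2 at 20 fmol, 0 to 8 at 40 fmol, 4 to 17 in direct RNA and 90 to 136 between controls.

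Thinning to 100 counts turned the excess isoform distance positive, to 0.0259 for gene-based, 0.0914 for transcript-based, 0.113 for exon-based and 0.545 at 40 fmol. Isoforms detected at 1 count were 1.30 times the control for TEQUILA, 1.05 for gene-based, 1.04 for master-based, 1.05 for transcript-based, 1.07 for exon-based and 1.02 in direct RNA. At deposited depth the ratios were 7.77, 1.46, 1.48, 1.41 and 1.41 in the main set, 0.921 at 40 fmol and 0.947 in direct RNA, and at 10 counts 0.964 at 40 fmol and 0.986 in direct RNA. Spike-in isoforms in direct RNA had 0.360 at 10 counts. The rho with length became 0.115 for exon-based and -0.00411 at 40 fmol with the most abundant transcript, and -0.0364 at 40 fmol and -0.233 in direct RNA on listed genes of the splicing lists. Genes overlapping targets on those lists had odds ratios of 9.15 for TEQUILA, 3.99 for gene-based, 2.24 for master-based, 3.30 for transcript-based, 3.53 at 20 fmol, 2.06 at 40 fmol and 4.34 in direct RNA, and 4.53 at 40 fmol on the same strand. No odds ratio exists for the exon-based design, which has no called gene. That set counts listed genes beside a core target as neighbours. In the pooled BT549 columns the median log2 share ratio under TEQUILA of receptor tyrosine kinases with mesenchymal-associated genes went from 0.14 to -0.25 with genes of at least 100 counts in the control column.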

Other observations

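The composition of spike-in counts, the mean transcript length and the share not annotated were chosen only after the result was seen.

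Direct RNA and cDNA controls treated spike-ins differently. ERCC spike-ins took 70.7% of spike-in counts in cDNA controls of the main set and 7.42% in direct RNA controls, the SIRV isoform mix 23.2% and 87.0%, and long SIRVs 6.08% and 5.53%. In direct RNA with gene-based sampling the parts were 27.3%, 59.2% and 13.5%. The coefficient of variation over SIRV isoforms was 0.731 ± 0.0746 (SD, n = 4) in main controls, 1.01 with gene-based, 1.29 with master-based and 0.761 with exon-based sampling. In direct RNA it was 0.264 in controls and 1.30 with gene-based sampling.

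TEQUILA libraries had a mean transcript length of 2997 b against 2298 b ± 43.4 in controls, and 16.6% ± 0.39 of their counts in transcripts that are not annotated. Gene-based libraries had 2137 b. Across the genes of the splicing lists, rho between TEQUILA's log2 fold and control abundance was -0.551 (-0.657 to -0.414), but over all 275 listed genes it was -0.0147 (-0.142 to 0.113). Genes are not independent replicates.

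In direct RNA, SFPQ-211 took 0% of SFPQ counts in controls and a mean of 21.2% with gene-based sampling, all of it from 1 library of 2. SFPQ-201 and SFPQ-211 held equal shares of 22.7% ± 2.57 in half-flow-cell cDNA controls. PRPF4-202 went from 0% to 36.9%, from 22.5 counts.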
